A study of Homo sapiens with 6 samples.

How the data were processed

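The series measured gene expression by RNA sequencing in 6 libraries of macrophages derived from U937 cells, 3 from vehicle controls and 3 from a STAT3 knockdown. Per the labels' protocols, both kinds of U937 monocyte were differentiated with the phorbol ester PMA, total RNA was extracted with a column kit, and libraries were made with a stranded mRNA kit and sequenced on a NovaSeq instrument. The authors deposited one table of raw read counts per gene with a gene length, named by gene symbol; per the file header its columns are replicates 1 to 3 of each group. Per the submitters' processing notes, the tools were CASAVA, STAR 2.5.2b, featureCounts 1.5.1 and edgeR, on the genome build hg19. The construct in the control cells, the number of constructs used for the knockdown, the gene annotation, the strand setting of the counting, any filter on reads and the treatment of reads that map to several genes are not given in the sources used here. Reads shared by near-identical genes, such as CCL3 and CCL4 copies, HLA genes, NCF1 and the FCGR family, could therefore be split or lost, and reads of a gene and its antisense partner may be counted together.

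The counts were used as deposited. Total counts ran from 16315156 to 23620665 per library, and all per-sample columns were mapped to a sample by the names in the header. Genes were filtered with filterByExpr at its defaults, scaled by the trimmed mean of M values (TMM), with factors from 0.937 to 1.065, and tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) on group alone over all 6 libraries. Genes with an adjusted p (Benjamini-Hochberg over 12899 tested genes) under 0.05 are called changed, and a further count asks for at least a 2-fold change. The standard error of a log2 fold change is the one implied by its F statistic. Levels are CPM, counts scaled by library total and TMM factor, with SD over 3 libraries, and log2 CPM for principal components and distances used a prior count of 2. For genes with under 10 counts in 1 group, ratios are of summed counts over summed scaled library sizes, with exact binomial 95% intervals that cover counting error only. In the one case of a group at 0 counts, the ratio was taken against 3 counts over the group.

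Gene lists, 52 in all with 1285 distinct genes, were written before the data were examined, as were the design, the alternatives and the rule for named genes. Symbols were matched to the table, also through older names, and 16 found no match. The 49 lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, and again with the correlation estimated per list; fry tested each list on its own. A further 3 lists, of ribosome biogenesis and translation genes, were added after the first results were seen and tested apart from these. For each list, calls are given over all genes tested and adjusted over the list alone. The naming rule took STAT3; fixed genes of the pathway and of macrophages; the 10 genes with the largest log2 fold change in each direction among those called, with an average log2 CPM of at least 1 and CPM that did not overlap between groups; the 10 genes with the smallest p; and up to 4 called members of each list in order of p. Other genes are said to be chosen after their values were seen. Some genes that the rule or the lists name are not reported here.

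Alternatives to the main analysis were DESeq2-style size factors, upper-quartile factors and library totals in edgeR; DESeq2 1.42.0; limma voom; robust dispersion; no low-count filter except genes at 0 in every library; at least 50 counts in 3 libraries; a replicate block; an adjusted p under 0.01; glmTreat against a fold of 1.5; each library left out in turn; and, added after the data were seen, removal of the trend of each library with GC content and gene length. GC content came from GENCODE release 29, matched by symbol for 97.3% of tested genes, and lengths from the deposited table; no coordinates were used, as that annotation is of another build. In counts simulated for the comparison of knockdown with vehicle control over 12899 genes, 200 of them changed, edgeR recovered 46.3% of the genes changed 1.5-fold, 77.6% of those changed 2-fold and 100% of those changed 4-fold, and 9.1% of its calls were false. The real comparison called 57.5% of tested genes, far more than were changed in the simulation, so these rates need not hold for the real calls. No pair of libraries agreed within sampling noise: over genes with at least 20 pooled counts, chi-square per degree of freedom was 4.85 to 32.9 within groups. Figures were drawn with matplotlib 3.10.9.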

Results

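RNA was sequenced from macrophages derived from the human U937 line, with 3 libraries from a STAT3 knockdown and 3 from a vehicle control. U937 cells are monocyte-like cells established from a histiocytic lymphoma, and the phorbol ester PMA drives them towards a macrophage state. STAT3 is a transcription factor that cytokine receptors activate through Janus kinases, and the design asks which transcripts depend on it in these cells. Total gene counts were 19403198, 19878053 and 22188965 in control replicates 1, 2 and 3 and 17112592, 23620665 and 16315156 in knockdown replicates 1, 2 and 3. Of 27140 genes, 19491 had a count and 12899 had enough counts to be tested. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. What construct the control cells carry is not given in the sources used here, so the fold changes include any effect of the knockdown construct other than the loss of STAT3.

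The knockdown and control libraries lay far apart. The first principal component held 84.9% of the variance of log2 CPM (a gene's counts scaled to a common library size), with scores of -54.4 to -50.4 in the controls and 44.1 to 57 in the knockdown. Across genes, which are not independent replicates, Pearson's r was 0.985 to 0.995 within groups and 0.922 to 0.937 between them. Knockdown replicate 3 stood furthest from its own group, at root mean square distances of 0.406 and 0.453 (log2) from replicates 1 and 2, which were 0.311 apart. Knockdown replicate 1 held more of some RNA without long poly(A) tails, with 129 unscaled CPM on replication-dependent histone genes and 1254 on the mitochondrial ribosomal RNA RNR1. On histone genes the other 5 libraries held 41 to 72.8. RNR1 held 376 to 399 in the controls and 451 and 506 in knockdown replicates 2 and 3. Small nucleolar and nuclear RNA held 68.8 to 70.2 in the controls and 129, 85.1 and 112 in knockdown replicates 1, 2 and 3. RNR2, also mitochondrial ribosomal RNA, took 0.636% to 0.68% of control libraries and 1.094%, 0.932% and 0.962% of knockdown libraries. RNR1, RNR2 and these small RNA, chosen after their values were seen, were thus higher in every knockdown library than in any control.

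STAT3 messenger RNA fell to 25% of its control level. It measured 188, 172 and 188 CPM in control replicates 1, 2 and 3 and 46.4, 45.4 and 45.3 CPM in knockdown replicates 1, 2 and 3, or 183 ± 9.25 against 45.7 ± 0.617 CPM (SD, n = 3 each). The log2 fold change was -2.00 (SE 0.06), with an edgeR quasi-likelihood adjusted p = 1.98e-07 after Benjamini-Hochberg correction. An exact two-sided permutation test of log2 CPM gave p = 0.1, the smallest value that 20 arrangements of 3 against 3 libraries allow. By size of fold, STAT3 ranked 423 among the 3327 genes that fell.

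**Figure D1:**
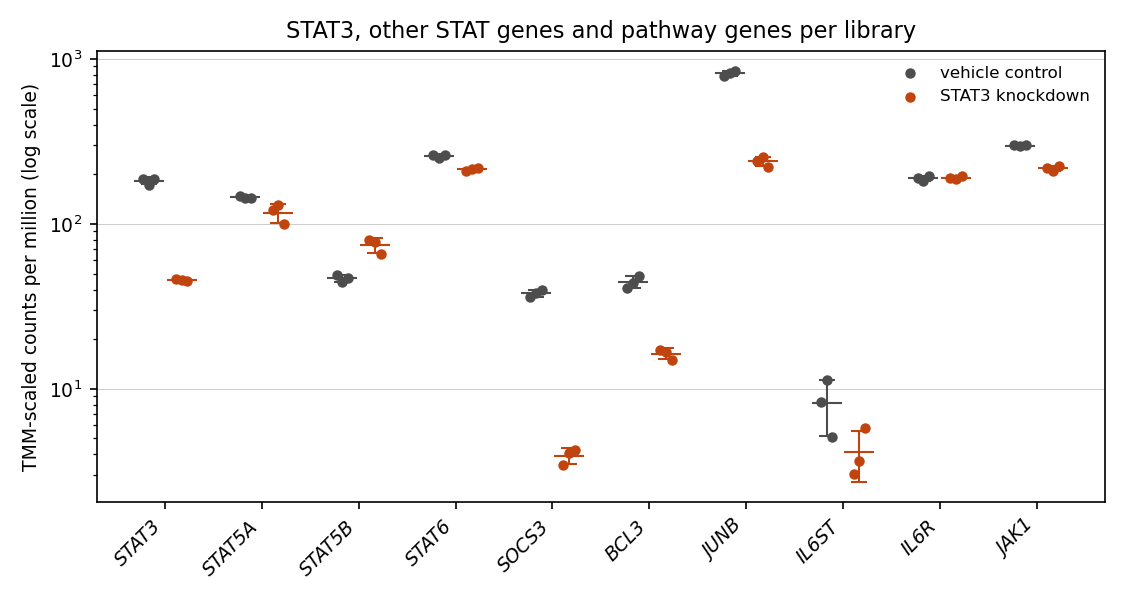
TMM-scaled CPM (log axis) of STAT3, other STAT genes and pathway genes in each of the 6 libraries; dots are libraries, horizontal bars the group mean and whiskers 1 SD (n = 3 per group). STAT3 sits near 183 CPM in the vehicle control and near 45.7 CPM in the knockdown, while IL6R lies at 189 and 191 CPM.

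In the knockdown 20 of 22 tested chemokine genes and 15 of 22 inflammatory cytokine genes fell, and 12 of 20 genes of undifferentiated myeloid cells rose. The cytokine IL1B fell 92.6-fold and the neutrophil chemokine CXCL8 fell 60.1-fold. The proto-oncogenes MYC and MYB rose 11.5-fold and 11.3-fold. Past an adjusted p of 0.05 were 7421 genes, 57.5% of those tested, of which 4094 rose and 3327 fell in the knockdown. At least a 2-fold change was seen for 1038 genes that rose and 1149 that fell, and at least an 8-fold change for 38 and 204, or 38 and 195 with genes at 3 or fewer counts in a group set to the near bound of their interval. CPM did not overlap between the groups for 8255 genes (64%), where chance gives 10%. Scaling by library totals alone moved the median log2 fold change of all tested genes up by 0.135 and raised the share of higher calls from 55.2% to 66.6%. With DESeq2-style size factors, DESeq2 and the GC and length correction more genes fell than rose, at 3619 higher and 3690 lower, 3363 and 3515, and 4140 and 4369.

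**Figure D2:**
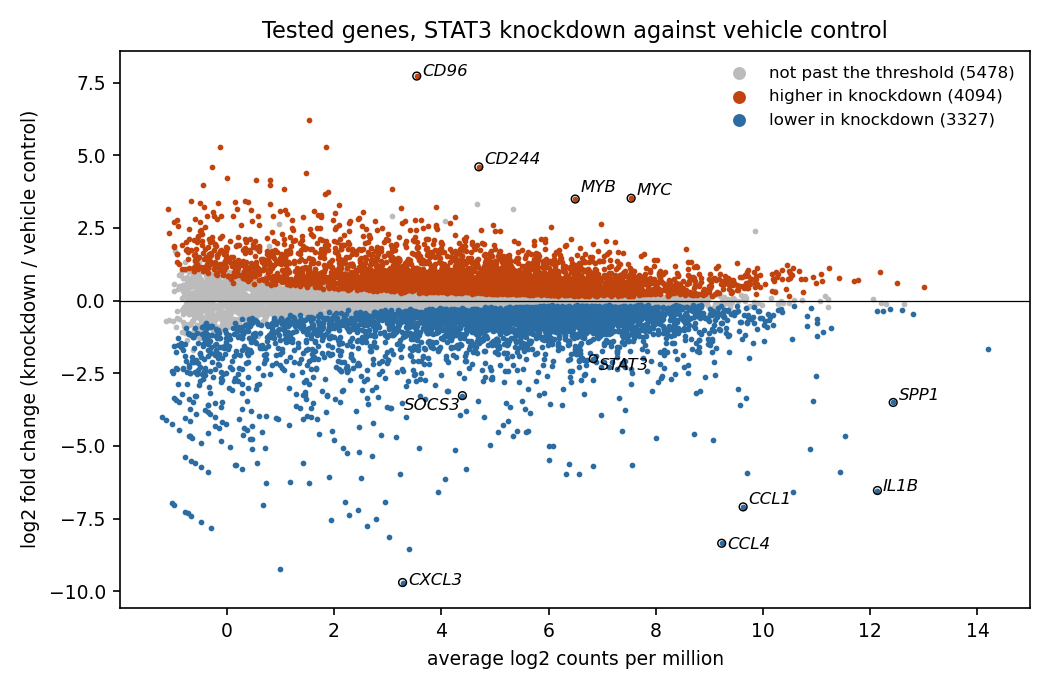
Log2 fold change (knockdown over vehicle control) against average log2 CPM for the 12899 tested genes; each dot is a gene, red for 4094 that rose, blue for 3327 that fell and grey for those not past an adjusted p of 0.05. CCL1, CCL4 and IL1B lie at the lower right, with log2 fold changes of -7.10, -8.35 and -6.53.

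Other STAT genes moved unevenly. STAT2 fell by 0.85 on the log2 scale (SE 0.08), STAT6 fell by 0.27 (SE 0.05) and STAT5B rose by 0.66 (SE 0.09). STAT5A fell by 0.31 (SE 0.09, edgeR adjusted p = 0.0213), a call that ended under scaling by library totals (0.12) and without control replicate 1, 2 or 3 (0.0684, 0.0515 and 0.0528). For the list of other STAT genes camera gave adjusted p = 0.0718, and 0.223 with an estimated correlation. These genes were also past the threshold adjusted over the list alone. The list passed without knockdown replicate 2 (camera adjusted p = 0.0382), without a low-count filter (0.0231) and after the GC and length correction (0.0332).

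Receptors, kinases and regulators of the pathway were mostly lower. IFNGR2, a chain of the interferon-gamma receptor, fell 3.16-fold and CSF2RB, the common beta chain of the GM-CSF, IL-3 and IL-5 receptors, fell 4.28-fold, while CSF3R, the G-CSF receptor, rose with a log2 fold change of 1.28 (SE 0.12). JAK1 fell by 0.46 (SE 0.05) and TYK2 by 0.65 (SE 0.06). The shared signalling chain IL6ST was low, at 8.26 ± 3.11 and 4.15 ± 1.42 CPM, with a log2 fold change of -0.99 (SE 0.32, edgeR adjusted p = 0.0288). That call ended under library totals (0.064), with a replicate block (0.0733), without control replicate 1 or 2 (0.0759 and 0.107) and without knockdown replicate 1 or 2 (0.0909 and 0.0507). IL6R, the interleukin-6 receptor, measured 189 ± 5.88 and 191 ± 3.83 CPM (edgeR adjusted p = 0.803), with a sign that turned under DESeq2-style size factors and without control replicate 2 or knockdown replicate 2, among others, and a call as higher with library totals (0.0289). Of 19 tested receptors and kinases 13 fell and 1 (CSF3R) rose, with 14 changed adjusted over the list alone (camera adjusted p = 0.00172, or 0.0558 with an estimated correlation). Among 19 negative regulators 12 fell and PIAS3 and SOCS7, chosen after their values were seen, rose, with 14 changed adjusted over the list alone (camera adjusted p = 0.00172, or 0.0558 with an estimated correlation). SOCS3, an inhibitor of the interleukin-6 signal, fell from 37.9 ± 1.95 to 3.92 ± 0.432 CPM, and CISH and SOCS1 fell 3.32-fold and 4.24-fold.

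Textbook STAT3 targets fell as a group. Of 27 tested, 19 fell and 3 rose, 24 changed when adjusted over the list alone, and the median log2 fold change was -0.88 (camera adjusted p = 5.72e-10, and 0.0245 with an estimated correlation). The adhesion molecule ICAM1 fell 8.26-fold, the kinase gene PIM2 fell 6.17-fold, JUNB fell from 816 ± 24.6 to 239 ± 16.3 CPM and BCL3 from 44.4 ± 3.67 to 16.3 ± 1.25 CPM. The exceptions were MYC, at 29.8 ± 1.12 and 342 ± 55.3 CPM (log2 fold change 3.52, SE 0.13, edgeR adjusted p = 3.19e-07), and BCL2 and BATF, chosen after their values were seen, which rose by 0.97 and 0.31. BATF was not called after correction for GC content and length (edgeR adjusted p = 0.472).

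Chemokine transcripts fell almost throughout. Of 22 tested, 20 fell, 1 rose and 1 did not pass, 21 changed adjusted over the list alone, and the median log2 fold change was -3.90, or 6.7% of the control level (camera adjusted p = 6.56e-53, and 0.0245 with an estimated correlation). CCL1 fell from 1573 ± 104 to 11.5 ± 0.874 CPM, CCL3 from 3651 ± 136 to 106 ± 2.5 CPM and CCL4 from 1197 ± 76.2 to 3.66 ± 0.729 CPM. CCL3 and CCL4 have near-identical gene copies, so their separate levels are uncertain. The monocyte attractant CCL2 fell 6.08-fold and CCL24, an eosinophil attractant, fell 14.6-fold. Only 1 knockdown count was seen for CXCL3 against 1126 in the controls, a ratio of 1150 (95% counting interval 205 to 45400), and 3 for CCL8 against 938, a ratio of 319 (109 to 1550). The riser was CCL23, chosen after its values were seen, at 2.23 ± 0.547 and 3.91 ± 0.316 CPM. Setting members with 3 or fewer counts to their bound left the median at -3.90, and testing without a low-count filter gave -2.65. Together the listed chemokines took 1.61% to 1.77% of each control library and 0.146% to 0.166% of each knockdown library.

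Inflammatory cytokines and NF-kB target genes fell with them. IL1B went from 8896 ± 724 to 96.1 ± 8.78 CPM (log2 fold change -6.53, SE 0.12, edgeR adjusted p = 2.33e-08), CXCL8 from 5437 ± 602 to 90.6 ± 37.6 CPM and TNF from 538 ± 28.1 to 83.3 ± 8.72 CPM. LIF, OSM and TNFSF15 fell 22.5-fold, 22.8-fold and 24-fold. IL6 had 4 counts in the knockdown against 529, a ratio of 135 (95% counting interval 52.3 to 496), and IL1A had 3 against 1225, a ratio of 416 (142 to 2020). Of 22 tested cytokines 15 fell, 18 changed adjusted over the list alone and the median was -3.04, or -2.23 without a low-count filter (camera adjusted p = 2.9e-24, and 0.0245 with an estimated correlation). The cytokines that rose were IL12A, IL18 and IL32, with log2 fold changes of 1.58, 1.54 and 0.24; IL12A and IL32 were chosen after their values were seen, and IL32 lost its call under DESeq2 (adjusted p = 0.14), under its size factors and under the GC and length correction, with the replicate block and without any 1 of control replicates 1 and 2 or knockdown replicates 1 and 2. Among 29 NF-kB feedback and target genes 28 fell, also adjusted over the list alone, with a median of -1.61 (camera adjusted p = 4.97e-35, and 0.0183 with an estimated correlation). Examples were IER3, which fell 12-fold, SOD2, the mitochondrial superoxide dismutase, which fell 10.2-fold, and TNFAIP3, the NF-kB inhibitor A20, which fell 3.41-fold. Immediate early genes fell in 23 of 29 cases and rose in 3 (DUSP2, FOSL2 and MYC, the first pair chosen after their values were seen), with 27 changed adjusted over the list alone and EGR3 down 31.7-fold and DUSP5 down 4.95-fold (camera adjusted p = 5.05e-23, and 0.0183 with an estimated correlation).

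Genes that restrain inflammation were lower too. IL1RN, the interleukin-1 receptor antagonist, fell from 1034 ± 75.5 to 37.2 ± 1.72 CPM and DUSP1, a phosphatase of MAP kinases, fell 6.52-fold. IL10 rose from 3.22 ± 0.561 to 5.45 ± 0.769 CPM (log2 fold change 0.75, SE 0.18, edgeR adjusted p = 0.00666), as did MERTK and TSC22D3, which were chosen after their values were seen. Of 23 tested anti-inflammatory and interleukin-10 response genes 17 fell and 3 rose, with 21 changed adjusted over the list alone (camera adjusted p = 8.21e-11, and 0.0245 with an estimated correlation). Markers of both activation states fell. For classical (M1) activation 14 of 19 fell and 16 changed adjusted over the list alone, with KYNU, an enzyme of tryptophan breakdown, down 51.4-fold (camera adjusted p = 1.69e-15, and 0.0245 with an estimated correlation). IRF1, chosen after its values were seen, rose by 0.28 (edgeR adjusted p = 0.0353, but 0.121 under DESeq2) and lost its call in 8 alternatives, among them those without control replicate 1 or 2 or knockdown replicate 1 or 2. For alternative (M2) activation 14 of 16 fell, STAB1 (chosen after its values were seen) rose and 15 changed adjusted over the list alone, with CLEC10A down 6.09-fold (camera adjusted p = 3.82e-08, and 0.0245 with an estimated correlation). CD163, a haemoglobin scavenger receptor, fell from 13.3 ± 1.01 to 7.6 ± 1.88 CPM, and the mannose receptor MRC1 had 0 counts in every library.

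**Figure D3:**
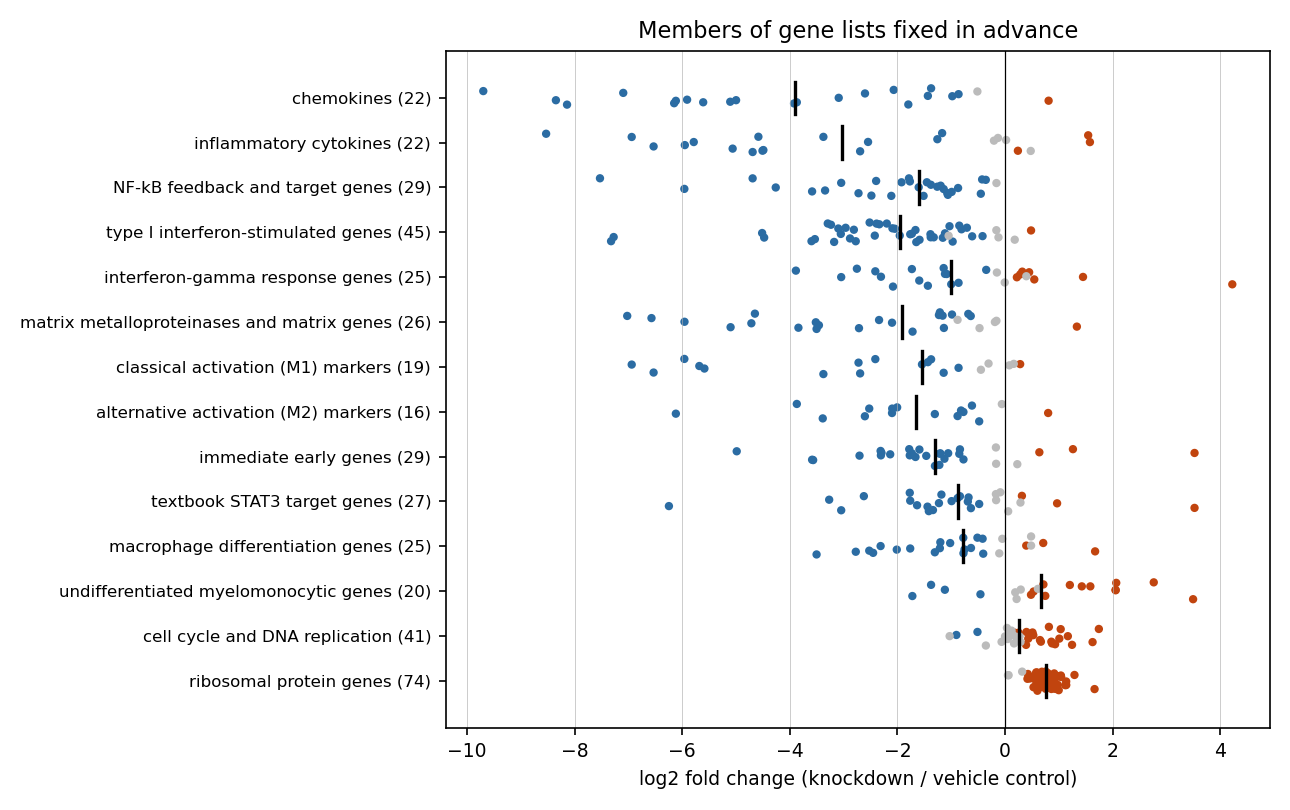
Log2 fold changes (knockdown over vehicle control) of the tested members of 14 gene lists fixed in advance; each dot is a gene, red where it rose, blue where it fell and grey where it did not pass, and black bars are list medians. Chemokines reach furthest down, with a median of -3.90, and ribosomal protein genes cluster above 0 with a median of 0.76.

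Type I interferon-stimulated genes fell broadly. Of 45 tested, 40 fell and 1 rose, 42 changed adjusted over the list alone, and the median log2 fold change was -1.96 (camera adjusted p = 6.51e-30). That call was lost with an estimated correlation (adjusted p = 0.0513 with an estimated correlation). The antiviral enzyme genes OAS2 and OAS3 fell 9.05-fold and 7.37-fold, the ubiquitin-like modifier ISG15 fell from 437 ± 57.8 to 50.9 ± 0.385 CPM, and the transcription factor IRF7 fell 5.73-fold. IFITM2, chosen after its values were seen, rose by 0.48. Among 25 interferon-gamma response genes 15 fell and 7 rose, with 22 changed adjusted over the list alone and GBP2 down 6.75-fold (camera adjusted p = 0.000105, but 0.102 with an estimated correlation). The count of those that rose dropped to 4 without control replicate 1 or 2, without knockdown replicate 2, and with the size factors of DESeq2.

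Macrophage differentiation genes fell while genes of undifferentiated myelomonocytic cells rose. SPP1 (osteopontin) fell from 10129 ± 481 to 893 ± 204 CPM, the co-receptor CD14 from 15.1 ± 0.957 to 2.75 ± 0.258 CPM and the integrin ITGAM from 351 ± 17.1 to 173 ± 12.6 CPM. The transcription factor gene CEBPB fell 3.39-fold and EGR2 fell 2.3-fold. Of 25 differentiation genes 18 fell and FABP4, FABP5 and GPNMB, chosen after their values were seen, rose, with 21 changed adjusted over the list alone and a median of -0.77 (camera adjusted p = 1.17e-07, and 0.0245 with an estimated correlation). FABP4 lost its call with the replicate block (edgeR adjusted p = 0.0917), without control replicate 1 or 3 (0.133 and 0.142) and without knockdown replicate 3 (0.0863). CD68 and ITGB2, chosen after their values were seen, measured 250 ± 3.55 and 241 ± 18.3 CPM, and 5239 ± 166 and 4859 ± 311 CPM; both turned sign when scaled by library totals, CD68 also without knockdown replicate 3, and both were called lower after the GC and length correction.

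The progenitor factor MYB rose from 14.7 ± 0.632 to 166 ± 2.11 CPM (log2 fold change 3.49, SE 0.07, edgeR adjusted p = 2.7e-08). The growth factor gene CLEC11A rose from 51.9 ± 1.46 to 216 ± 9.56 CPM, and the transcription factor genes GFI1 and SOX4 rose by 2.07 and 2.05 on the log2 scale. Of 20 tested granule and progenitor genes 12 rose and 4 fell, with 16 changed adjusted over the list alone and a median of 0.66 (camera adjusted p = 2.33e-06, and 0.0245 with an estimated correlation). Those that fell, chosen after their values were seen, were the granule protein genes ELANE, MPO and SRGN and the transcription factor gene CEBPE. MPO was below 1 CPM in both groups and lost its call under DESeq2 (adjusted p = 0.124), without a low-count filter, with the replicate block, and without control replicate 3 or knockdown replicate 2 or 3. Macrophage and myeloid transcription factors fell in 20 of 32 cases and rose in 6, with 27 changed adjusted over the list alone and BHLHE40 down 2.53-fold (camera adjusted p = 4.64e-05, and 0.0294 with an estimated correlation).

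**Figure D4:**
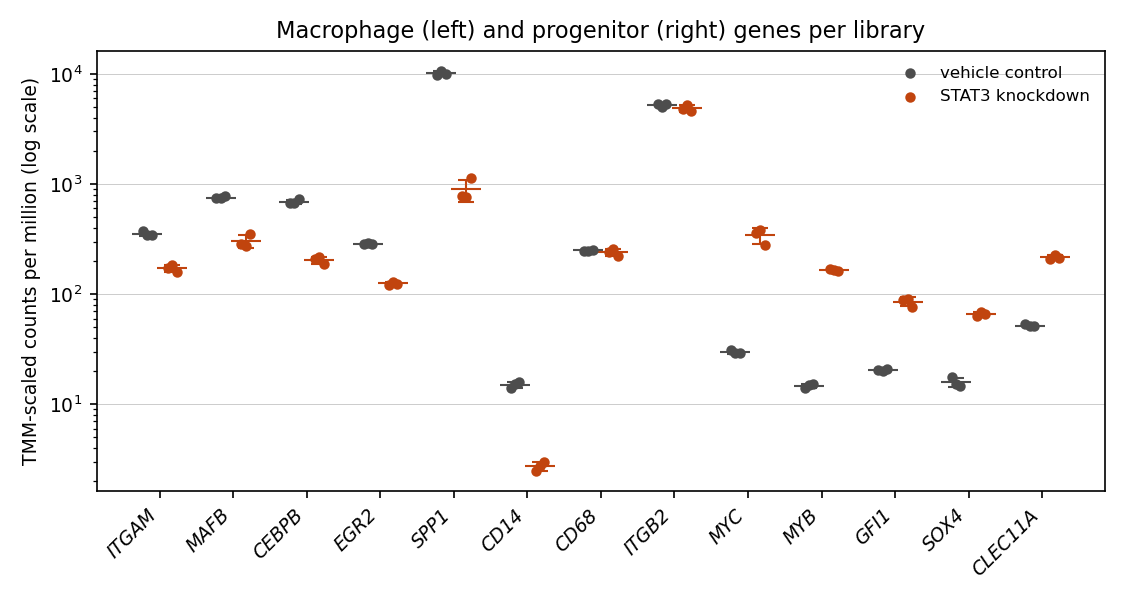
TMM-scaled CPM (log axis) of macrophage genes (ITGAM to ITGB2), MYC, and progenitor genes (MYB to CLEC11A) in each library. MYC is not on the list of granule and progenitor genes. Dots are libraries, bars means and whiskers 1 SD (n = 3 per group). SPP1 drops from 10129 to 893 CPM and MYB climbs from 14.7 to 166 CPM, while CD68 and ITGB2, which turned sign when scaled by library totals, did not pass the threshold.

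Fc and complement receptor genes fell, and pattern recognition and phagocyte killing genes were mostly lower. The receptor TREM1, which amplifies inflammatory signals, fell 51-fold, and CLEC4E had 6 counts in the knockdown against 423, a ratio of 71.8 (95% counting interval 32.7 to 197). Among 24 pattern recognition receptors and adaptors 17 fell and IRAK1, NOD1, TLR5 and TMEM173, chosen after their values were seen, rose, with 21 changed adjusted over the list alone (camera adjusted p = 5.17e-08, but 0.0732 with an estimated correlation). TMEM173, at 176 ± 5.13 and 197 ± 10.5 CPM, lost its call in 9 alternatives, DESeq2 (adjusted p = 0.328) and those without any 1 control replicate or knockdown replicate 1 or 2 among them, and turned sign in the GC and length correction. Of 19 Fc and complement receptors 15 fell and FCGRT, chosen after its values were seen, rose, with 16 changed adjusted over the list alone, FCAR down 5.05-fold and FCGR2A, whose family shares sequence, down 3.36-fold (camera adjusted p = 8.26e-12, and 0.0245 with an estimated correlation). FCGRT was not called after the GC and length correction (edgeR adjusted p = 0.0801). CYBB, a subunit of the phagocyte NADPH oxidase, fell 12.6-fold; 14 of 17 genes of oxidase and killing fell and BPI and CAMP, chosen after their values were seen, rose, with 16 changed adjusted over the list alone (camera adjusted p = 1.18e-07, but 0.0558 with an estimated correlation). Chemokine and chemoattractant receptors fell in 9 of 13 cases, CCR1 by 4.08-fold, and rose in 4 (CX3CR1, CXCR2, CXCR4 and LTB4R, chosen after their values were seen), with 13 changed adjusted over the list alone (camera adjusted p = 1.41e-05, but 0.0776 with an estimated correlation). CXCR2 lost its call under DESeq2 (adjusted p = 0.0789) and without control replicate 1 or 3.

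Matrix metalloproteinase and matrix genes fell as a group. The collagenase MMP1 fell from 3003 ± 161 to 31.6 ± 4.01 CPM, MMP10 and MMP7 fell 62.2-fold and 26.3-fold, and the urokinase receptor PLAUR fell 11-fold. MMP2, chosen after its values were seen, rose from 41.1 ± 1.61 to 104 ± 9.39 CPM. Of 26 matrix metalloproteinases and matrix genes 21 fell and 1 rose, with 23 changed adjusted over the list alone (camera adjusted p = 4.83e-26, and 0.0183 with an estimated correlation). Of 12 angiogenic and growth factors 6 fell, 1 (SEMA4D, chosen after its values were seen) rose and 7 changed adjusted over the list alone, with HBEGF down 13.5-fold and INHBA down 44.6-fold (camera adjusted p = 1.26e-05, and 0.0294 with an estimated correlation). The median log2 fold change of this list was -0.44 (95% bootstrap interval over the list -3.6 to 0.03), the mean was -1.48, and without a low-count filter the median was 0.01 beside a downward test. Integrins and adhesion molecules fell in 13 of 24 cases and rose in 7, with 20 changed adjusted over the list alone and ITGA6 down 2.49-fold (camera adjusted p = 0.012, but 0.252 with an estimated correlation and a call lost under limma voom). Costimulatory and checkpoint ligands fell in 14 of 21 cases and rose in 5 (CD70, LGALS9, LILRB2, TNFRSF14 and TNFSF4, chosen after their values were seen), with 20 changed adjusted over the list alone and HAVCR2 down 2.44-fold (camera adjusted p = 0.00188, but 0.0558 with an estimated correlation). LGALS9 and TNFRSF14 lost their calls in 8 and 10 alternatives, among them DESeq2 (adjusted p = 0.17 and 0.105), the GC and length correction (0.723 and 0.254) and those without control replicate 1 or 2 or knockdown replicate 1 or 2, TNFRSF14 also without control replicate 3, and the count that rose was 3 without control replicate 1 or 2 and without knockdown replicate 1 or 2.

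Ribosomal protein genes rose together. Of 74 tested, 71 rose and none fell, also adjusted over the list alone, with a median log2 fold change of 0.76 (camera adjusted p = 4.16e-17, but 0.248 with an estimated correlation). RPS3A rose from 425 ± 25.9 to 1040 ± 117 CPM and RPL5 from 554 ± 24.9 to 976 ± 29.9 CPM. The list took 4.63% to 4.92% of each control library and 8.18% to 9.45% of each knockdown library. Cell cycle and DNA replication genes rose in 21 of 41 cases, MCM2 from 94.3 ± 2.88 to 223 ± 21.5 CPM, and fell in 2, CDK1 and RRM2, chosen after their values were seen, with 23 changed adjusted over the list alone (camera adjusted p = 0.00188, but 0.283 with an estimated correlation). CDK1 lost its call in 7 alternatives, among them library totals (edgeR adjusted p = 0.104) and those without control replicate 1 or 2 or knockdown replicate 1 or 2. Nuclear-encoded oxidative phosphorylation genes rose in 39 of 76 cases and fell in 8, with 47 changed adjusted over the list alone (camera adjusted p = 0.0427, but 0.681 with an estimated correlation), a call that ended in 8 of 15 settings, among them leaving out control replicate 1 or 2 or knockdown replicate 1 or 2. In the p53 target and cell cycle inhibitor list, CDKN1A (p21) fell from 661 ± 43.8 to 117 ± 0.413 CPM and BTG2 fell 4.91-fold; 11 of 25 fell and CDKN2C, FDXR and XPC, chosen after their values were seen, rose, with 14 changed adjusted over the list alone (camera adjusted p = 0.00101, but 0.0542 with an estimated correlation).

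The largest rises included receptors known from lymphocytes. CD96, an immunoglobulin superfamily receptor known from T and natural killer cells, rose from 6 counts over the controls to 1372 over the knockdown, a ratio of 224 (95% counting interval 103 to 613), and CD244, a receptor of natural killer cells, rose from 2.04 ± 0.566 to 49.8 ± 3.42 CPM. The muscle LIM protein gene CSRP3 rose from 4 to 333 counts, a ratio of 81.7 (31.6 to 302). SNORA10, SNX32, NEGR1, HAL, DEPTOR and LOC100506688 rose with log2 fold changes of 5.27, 4.39, 3.85, 3.85, 3.75 and 3.67. SNORA10 lies within a host gene, so its counts may include reads of the host, and antisense reads cannot be told apart since the strand setting of the counting is not given. The largest falls outside the groups above were in IL2RA, a chain of the interleukin-2 receptor, with 3 counts against 709, a ratio of 241 (82.1 to 1170), PANX2 with 2 against 437, a ratio of 223 (61.3 to 1840), CD226 with 3 against 550, a ratio of 187 (63.6 to 909), TNFAIP6 with 4 against 793, a ratio of 202 (78.6 to 743), and SPRED1 with 4 against 625, a ratio of 159 (61.9 to 586). RGS16, a regulator of G protein signalling, fell from 1635 ± 64.5 to 27 ± 0.601 CPM and had the smallest p-value of all genes (edgeR adjusted p = 7.27e-09), and the amino acid transporter SLC43A2 fell 9.37-fold. The fitted log2 fold changes of several of these low-count genes rest on 1 library. CSRP3 gave 7.39 without control replicate 3, CXCL3 -11.59 without knockdown replicate 1, and SPRED1 -10.66, IL2RA -8.46, PANX2 -6.90 and IL1A -7.86 without knockdown replicate 2. Without knockdown replicate 3, TNFAIP6 gave -8.83, IL1A -9.45 and CCL8 -9.06.

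Markers of other cell types did not move one way. Among the tested lymphocyte markers CD4, CD79A and PAX5 rose and GNLY, GZMB and NKG7 fell, also adjusted over the list alone, with a median of 0.81 (0.13 without a low-count filter), a mean of -0.02 and an upward test (camera adjusted p = 0.532). PAX5 and NKG7 were chosen after their values were seen. Among 8 fibroblast and endothelial markers ACTA2 and ERG rose and CLDN5 and PDGFRB fell, also adjusted over the list alone, with a median of 0.50 (-0.07 to 0.98 over the alternatives), a mean of -0.29 and a downward test (camera adjusted p = 0.678). ACTA2 lost its call in 9 alternatives, among them DESeq2 (adjusted p = 0.0796), limma voom (0.0658) and those without any 1 control replicate or knockdown replicate 1 or 2. Of 6 dendritic cell markers CLEC10A and ZBTB46 fell, also adjusted over the list alone, with a median of 0.05, a mean of -0.48 and a downward test (camera adjusted p = 0.259). Epithelial markers with 2 tested genes, and erythroid and megakaryocyte markers with 4, were too few to test; their listed genes held 404 and 1987 counts over the controls and 392 and 1632 over the knockdown. Mitochondrially encoded protein genes had 0 members in the table used here.

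Of the 49 lists tested 31 passed the threshold, 27 lower and 4 higher in the knockdown, and 14 passed with an estimated correlation. Splits of the libraries that put both groups on both sides passed 7 to 32 lists with the preset correlation. The number of lists past the threshold therefore does not set the real grouping apart. These splits still hold unequal numbers of knockdown libraries on their sides, so they cannot decide whether such a camera call comes from the knockdown. The spread between replicates was small, with a biological coefficient of variation of 11.7%, so that small shifts also passed.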

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

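The GC and length correction was the alternative chosen after the data were seen. STAT3 stayed lower and past the threshold in every alternative run, with log2 fold changes of -2.10 to -1.86. The 7421 called genes ranged from 5595 (adjusted p under 0.01) to 8828 (without knockdown replicate 3), and from 6261 to 8828 when 1 library was left out. DESeq2 called 6878, limma voom 7571 and the GC and length correction 8509. Of the genes called both ways, CITED4 (0.32 to -0.18) and PPP1R35 (0.29 to -0.17), named after their values were seen, changed direction under that correction and none did in the other settings compared, and 82% to 99.8% of the main calls were kept in each setting compared. The replicate block gave 6091 calls, 6084 of them shared. Deviations of same-numbered libraries from their group mean correlated at -0.12, -0.32 and -0.43, which gives no sign that the numbers pair the samples. With 3 libraries per group these correlations depend on each other and cannot exclude pairing. Gene lists past the threshold went from 31 to 14 when the correlation between genes was estimated. Lists with an estimate below the preset 0.01 lost their call too. JAK-STAT receptors and kinases, with an estimate of -0.03, went from a camera adjusted p of 0.00172 to 0.0558. For such lists a higher correlation between genes is argued against as the cause of the lost call. A call lost with an estimated correlation therefore does not by itself show that the list's genes are correlated. What else differs between the 2 settings was not tested. Fry's mixed test, which asks another question, gave 48, and the other alternatives gave 30 to 46. The share of higher calls was 55.2% in the main analysis, 66.6% with library totals alone, which shifted the median of all genes by 0.135, 49.5% with DESeq2-style size factors and 48.9% with DESeq2, and the GC and length correction gave 4140 higher and 4369 lower, so which direction holds the majority depends on the scaling. Of 4432 pairs of a named gene and an alternative, 4294 kept direction and call, 126 lost the call, 3 gained it (IL6R with library totals, CD68 and ITGB2 with the GC and length correction) and 9 turned sign, in IL6R, TMEM173, CD68 and ITGB2. The log2 fold change of IL6R was -0.0283 with DESeq2-style size factors, -0.0283 with DESeq2, -0.0984 with the GC and length correction and 0.1532, called higher, with library totals (adjusted p = 0.0289); with 1 library left out it ran from -0.0093 (without control replicate 2) to 0.0361, and it was -9e-04 without knockdown replicate 2. TMEM173 gave -1e-04 with the GC and length correction and ITGB2 0.0263 with library totals. CD68 gave 0.0826 with library totals and -0.1393 to 0.0068 with 1 library left out, above 0 without knockdown replicate 3; the cause was not tested. Depth limits genes such as CXCL3, IL1A and CCL8, with 1 to 3 counts over the knockdown, whose ratios are known only within their counting intervals.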

Other observations

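The tests on undifferentiated cells and on the scaling of interferon-stimulated genes, and the GC and length test of macrophage differentiation genes, were chosen after the result was seen, the GC and length correction was added after the data were seen, and the 3 lists of ribosome biogenesis and translation genes were written after the first results were seen.

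Further lists held more genes that fell than rose. Heat shock and oxidative stress genes fell in 19 of 31 cases, with 25 changed adjusted over the list alone, SRXN1 down 2.95-fold, while CAT, the catalase gene, rose from 86.6 ± 2.44 to 224 ± 7.4 CPM (camera adjusted p = 2.19e-05, but 0.168 with an estimated correlation). DNAJB1, GPX1 and HSPD1, chosen after their values were seen, also rose. The unfolded protein response list fell in 20 of 29 cases and rose in 1, ASNS, chosen after its values were seen, with 25 changed adjusted over the list alone and ATF3 down 3.02-fold (camera adjusted p = 0.000125, but 0.0638 with an estimated correlation). Hypoxia response genes fell in 16 of 23 cases, also with 18 changed adjusted over the list alone, ADM by 7.72-fold, and MXI1 and NDRG1, chosen after their values were seen, rose, NDRG1 with its call lost in 5 alternatives, 3 of them without control replicate 1 or 2 or knockdown replicate 2 (camera adjusted p = 0.000226, but 0.0542 with an estimated correlation). Inflammasome and pyroptosis genes fell in 9 of 17 cases, NLRP3 by 2.2-fold, and IL18 and GSDMD (chosen after its values were seen) rose, with 11 changed adjusted over the list alone (camera adjusted p = 0.00203, but 0.125 with an estimated correlation). GSDMD was not called after the GC and length correction (edgeR adjusted p = 0.215). FTH1, the ferritin heavy chain, fell from 28621 ± 1878 to 9125 ± 748 CPM, yet the 17 iron and heme genes, with 9 lower, 4 higher (BLVRB, SLC40A1, SLC48A1 and STEAP3, the first pair chosen after their values were seen) and 13 changed adjusted over the list alone, did not pass (camera adjusted p = 0.173).

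Several groups held called genes in both directions and did not pass as lists. Complement was split: the components C2, C5, CFB, CFD and CFP rose and C3 and the receptors C3AR1 and C5AR1 fell, the first 4 chosen after their values were seen, with 8 of 10 changed adjusted over the list alone (median 0.35, mean 0.04, downward test, camera adjusted p = 0.259). CFB, under 2 CPM in both groups, lost its call under DESeq2 (adjusted p = 0.107) and without control replicate 1. HLA class II presentation had 5 of 11 lower (CD74, CTSS, HLA-DQA2, HLA-DRB1 and HLA-DRB5) and 4 higher (HLA-DMA, RFX5, RFXANK and RFXAP), with 9 changed adjusted over the list alone (camera adjusted p = 0.32); HLA-DQA2, HLA-DRB1, HLA-DMA, RFXANK and RFXAP were chosen after their values were seen. RFXANK lost its call in 6 alternatives: DESeq2 (adjusted p = 0.0842), edgeR with its size factors (0.055), the replicate block (0.0618), without control replicate 1 (0.0501), without knockdown replicate 2 (0.11) and the GC and length correction (0.51). HLA genes share sequence, and HLA-DQA2 had 1 knockdown count against 56, a ratio of 57.1 (95% counting interval 9.83 to 2290). HLA class I presentation fell in 10 of 21 cases and rose in 6, 16 in all adjusted over the list alone (camera adjusted p = 0.22). The remaining lists gave camera adjusted p = 0.0718 for glycolysis (11 lower and 4 higher of 25, which were ALDOC, LDHB, PFKL and SLC16A1, 15 adjusted over the list alone, with SLC2A3 down 3.23-fold) and 0.0718 for apoptosis regulators (15 lower and 5 higher of 29, which were BCL2, BCL2L11, BIK, CASP6 and TNFRSF10A, 20 adjusted over the list alone, with MCL1 down 2.53-fold). They gave 0.158 for autophagy (11 lower and 5 higher of 32, which were ATG16L2, ATG9A, GABARAP, UVRAG and WIPI1, 16 adjusted over the list alone), 0.158 for scavenger receptors (11 lower and 8 higher of 24, 20 adjusted over the list alone, with OLR1 down 31.4-fold) and 0.202 for lysosomal genes (16 lower and 10 higher of 32, 28 adjusted over the list alone). Lipid lists gave 0.641 for efflux and LXR/PPAR targets (9 lower and 7 higher of 23, 17 adjusted over the list alone), 0.765 for fatty acid synthesis (5 lower, which were ACSL1, ACSL3, ACSL4, DGAT2 and PLIN3, and 9 higher of 22, 14 adjusted over the list alone) and 0.828 for cholesterol biosynthesis (8 lower and 6 higher of 23, 14 adjusted over the list alone). Eicosanoid genes gave 0.705 (6 lower and 6 higher of 18, 12 adjusted over the list alone) although PTGS2, the inducible cyclooxygenase, fell 62.3-fold. Of 14 replication-dependent histone genes HIST1H2AC and HIST1H2BK fell, also adjusted over the list alone (camera adjusted p = 0.765), but without knockdown replicate 1 the count was 7 and the adjusted p 0.0468. Glycolysis, apoptosis regulators and the STAT family changed their call in 2, 4 and 3 of 15 settings. Of the members named in full above for glycolysis, apoptosis, autophagy and fatty acid synthesis, LDHB, CASP6 and ACSL1 came from the naming rule and the others were chosen after their values were seen. GABARAP, DGAT2, UVRAG, ATG9A, PLIN3, PFKL and WIPI1 lost their calls in 8, 5, 4, 3, 3, 2 and 2 alternatives. Leaving out knockdown replicate 2 ended the calls of GABARAP, UVRAG, ATG9A, PFKL and WIPI1, and knockdown replicate 1 those of GABARAP and DGAT2. Leaving out control replicate 1 ended those of GABARAP, UVRAG and WIPI1, replicate 2 those of GABARAP, DGAT2 and ATG9A, and replicate 3 those of UVRAG, DGAT2 and PLIN3.

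The joint fall of inflammatory and macrophage genes and rise of progenitor genes could reflect a mixed population or a population that differentiated less. For the chemokines a minority of undifferentiated cells is argued against as the whole cause, provided that the other cells kept control levels. The median chemokine kept 6.7% of its control level (95% bootstrap interval over the list 1.7% to 28.8%). A share under 50% of such cells would then leave 50% or more. Whether the other cells kept control levels was not tested, and a share of 50% or more stays open. A GC or length trend as the whole cause is argued against, with a median of -4 (-5.46 to -2.07) after correction. For the macrophage differentiation genes the trend is argued against as the whole cause too, with a median of -0.9 (-1.43 to -0.32) after correction against -0.77 before and the list still past the threshold (camera adjusted p = 2.04e-07). A minority of undifferentiated cells stays open for the list's median, since the median level kept was 58.5% (40.5% to 75.5%). Point estimates put 11 of 25 members under 50%. These were picked by that value with no allowance for its error, so their count cannot decide whether such a minority is the whole cause. Weaker differentiation of the whole population stays open: 12 progenitor genes rose, but undifferentiated libraries were not analysed here, so it and a direct loss of STAT3-dependent transcription cannot be told apart. Effects of the knockdown construct other than the loss of STAT3 stay open too, as untested, since what the control cells carry is not given in the sources used here.

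The lower type I interferon-stimulated genes may follow from less interferon. Scaling is argued against, with the list's median at -1.82 or below under every scaling tried, and so is a GC or length trend, with -2 (-2.51 to -1.33) after correction. Type I and III interferon genes held 45 counts over the controls and 3 over the knockdown, a ratio of 15.3 (4.91 to 76.9), or 32.5 (5.54 to 1310) without knockdown replicate 3. IFNB1, chosen after its counts were seen, had 6, 3 and 17 counts in the controls and 0, 0 and 0 in the knockdown, at least 8.83-fold lower against 3 counts over the group, or 4.74-fold without control replicate 3 and 5.2-fold without knockdown replicate 2. An exact binomial test (p = 4.69e-10) compares the reads of these libraries, not the conditions, and STAT2 and IRF7 transcripts were lower too, so the order of events is untested.

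Knockdown replicate 3 stood apart from replicates 1 and 2. A difference in depth is argued against, since after thinning all knockdown libraries to the smallest total its distance was still 1.35 times that between the other two. A GC content trend in that library stays open: its deviation followed GC content across genes (Spearman rho -0.64). Removing the trend cut its mean distance to the others from 0.429 to 0.336, while replicates 1 and 2 were 0.311 apart before and 0.303 after. The cut of 21.8% was under the 25% that had been set. That bar was hard to reach, as it asked for a distance near that between replicates 1 and 2. Leaving it out raised the calls from 7421 to 8828. The labels give no batch, and no biological explanation was tested.

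A wider rise of ribosome biogenesis genes was tested as a hypothesis beside the rise of MYC. Of 40 such genes 36 rose and 1 fell, with a median log2 fold change of 0.78 (camera p = 0.0219 with an estimated correlation). Translation initiation and elongation factors gave a median of 0.50 (p = 0.0387) and cytosolic aminoacyl-tRNA synthetases 0.43 (p = 0.191), both with an estimated correlation. Adjusted over these 3 lists the p-values with an estimated correlation were 0.058, 0.058 and 0.191, so none passed, while with the preset correlation they were 1.7e-10, 0.000159 and 0.00316. More ribosome production in the knockdown stays an open hypothesis.

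Across all 10 ways to split the 6 libraries into 3 and 3, 1 (the real one) gave as many called genes, 7421, and the highest other gave 0 in edgeR, 0 in limma voom and 995 at an unadjusted p under 0.05. For genes with at least a 2-fold change 1 split, the real one, gave 2187, and the highest other gave 0 in edgeR and 74 unadjusted. For lists past the threshold 3 splits gave as many as the real 31, with 32 as the highest other and 7 as the lowest, so the list count does not set the real grouping apart. The other splits still hold unequal numbers of knockdown libraries on their sides, which leaves part of the knockdown difference between them. Their list counts therefore cannot decide whether a camera call made with the preset correlation comes from the knockdown. With 10 splits no share under 0.1 is possible. Each other split puts libraries of both groups on both sides, so the group difference adds to the spread within each side. Few or no called genes were therefore likely in them, and they cannot test whether the real calls arose by chance.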
